A study of Homo sapiens with 6 samples.

How the data were processed

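The series holds 6 RNA-seq libraries of BEAS-2B cells, 3 labelled as controls and 3 as 15-KETE, each numbered 1 to 3 in the sample titles. Per the labels' protocols, RNA was isolated with a column kit and polyadenylated RNA was made into libraries with a SMARTer mRNA kit. The submitters' processing notes name cutadapt 1.9.1, HISAT2 2.2.1, HTSeq 0.6.1, SAMtools 0.1.19, StringTie 1.3.3b, Cufflinks and Cuffdiff 2.2.1, DESeq2 1.6.3, DESeq 1.18.0 and edgeR 3.4.6, with no role or order. Whether the counting used strand is not given in the sources used here, so reads of a gene and of its antisense partner cannot be told apart. Reads of near-identical copies, such as HSPA1A and HSPA1B, ribosomal protein genes and their pseudogenes, the AKR1C family, ACOT1 and ACOT2 or the metallothioneins, can be split between copies in ways that the notes do not describe.

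The authors deposited 1 table with 61806 Ensembl genes. Its raw counts, per the file headers, are whole numbers per gene and library that were not normalised. Its FPKM values, per the file headers, are fragments scaled to gene length and library total, and 100% of them lay within 0.01 of the FPKM recomputed from the count, the exonic gene size and the library total in the same table. Exonic gene size in bases comes from the same table and is the length meant below. It is a value per gene and not the length of a single transcript. The genome build is not given in the sources used here. Of the 58254 genes shared with GENCODE release 29, 100% lay on the same chromosome and 89.6% had the same start or the same end in GRCh38. Coordinates are printed as the table gives them, counted from 1. The table gave symbols for 41389 of its genes, and all gene names come from it.

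Library totals ran from 16844781 to 22876808 counts. The counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes with low counts were removed with filterByExpr by group, which left 15451 genes. Library sizes were scaled with trimmed means of M values (TMM), and the quasi-likelihood test with robust dispersions compared 15-KETE with control over all 6 libraries. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, with 0.05 as the threshold. CPM are counts scaled to the library's total over the tested genes and its TMM factor, and fold changes are 15-KETE over control on the log2 scale. Intervals are 95% intervals, and they measure the spread between these 6 libraries.

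Before the data were examined, 32 gene lists with 808 genes were fixed. They covered stress pathways, lipid and eicosanoid metabolism, inflammation, cell cycle, housekeeping complexes and markers of airway and other cell types, and all 808 genes were in the table. The 29 lists with at least 5 tested members were tested with limma 3.58.1's camera with a preset correlation between genes of 0.01, adjusted over the 29 lists, and again with an estimated correlation and with fry. Shares of mitochondrial, ribosomal protein, histone and top 10 gene counts were compared by exact two-sided permutation tests, whose smallest possible p with 3 against 3 libraries is 0.1. The single-library share intervals are Wilson intervals and cover counting error only.

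The rule for named genes was also fixed in advance. Because fewer than 20 genes passed the test, it took the 20 genes of smallest p and, in every fixed list, the member of smallest p. Genes named outside this rule were chosen after their values were seen, and the text says so.

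The groups share replicate numbers, so it was checked whether the numbers pair the libraries. Deviations from the group means over the tested genes correlated at 0.57, 0.646 and 0.722 between libraries numbered 1, 2 and 3, against -0.564 to -0.092 for libraries with different numbers. Deviations cancel out within a group, so high same-numbered values in part force low values between different numbers. Every same-numbered pair was over 0.1, so the numbers were taken to pair the libraries. The pairing comes from the titles and this check, and no label says what a number stands for. The fit with the replicate number as a block was planned as an alternative before the data were examined. No 2 libraries held identical columns or agreed within sampling noise, with a chi-square per gene of at least 2.62 between any 2 libraries.

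Other alternatives fixed in advance were DESeq2 1.42.0, limma-voom, limma-trend on log2(FPKM + 1), other size factors, no scaling, other filters on low counts, protein-coding genes alone, a 1.5-fold threshold in the test, another denominator for the shares, and leaving out each library in turn. Alternatives chosen after seeing the data were a correction for exonic length and GC content, with mgcv 1.9-3, and leaving out each same-numbered pair. The correction took from each library a smooth trend on exonic length and GC content, fitted on genes outside the fixed lists. GC content came from the GENCODE transcripts and was known for 15219 of the 15451 tested genes (98.5%). The gene test and the list test were tested on simulated counts with known changes drawn from these libraries' means and totals. Levels of sex-linked marker genes were left out.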

Results

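RNA was measured in BEAS-2B cells, an immortalised line of human bronchial epithelial cells, kept as controls or exposed to 15-KETE. 15-KETE, also called 15-oxo-ETE, is an oxidised metabolite of arachidonic acid with an electrophilic unsaturated ketone, which the dehydrogenase HPGD forms from the ALOX15 product 15-HETE. The labels give neither its dose nor the time of exposure. The control libraries held 18215997, 21780953 and 16844781 counts for replicates 1, 2 and 3, and the 15-KETE libraries 17861421, 22876808 and 17562525. Between 23024 and 25175 genes had counts in a library. No label says that the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

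The libraries stood apart by replicate number more than by treatment. The first principal component held 63.5% of the variance and set control replicate 2, at a score of 90.01, apart from the other libraries, at -43.35 to 18.36. The second held 19.63% and set both replicate 1 libraries, at 37.53 and 32.34, apart from the rest, at -25.74 to -7.53. In 5 of the 6 libraries the library of highest correlation was its same-numbered partner in the other group. The exception was 15-KETE replicate 2, which was nearest to control replicate 1 (r = 0.981 across genes, which are not independent replicates).

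**Figure D1:**
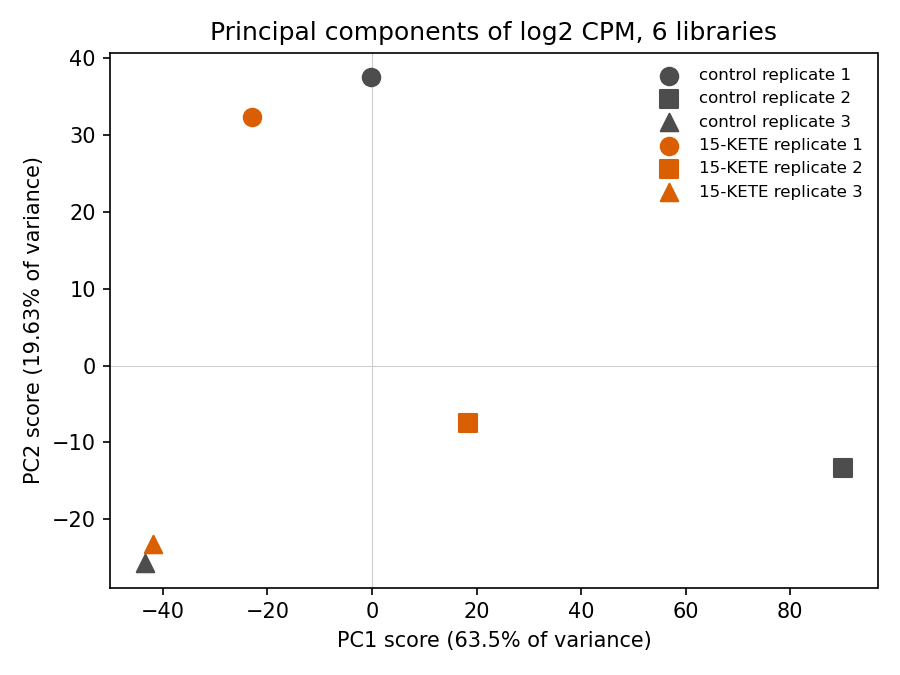
Scores of the 6 libraries on the first 2 principal components of log2 CPM, with controls in grey, 15-KETE in orange and a marker shape per replicate number. The axes give unitless scores with the percent of variance, and both replicate 3 libraries lie together while control replicate 2 lies alone at 90.01 on the first component.

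Ribosomal protein transcripts took 3.94% ± 0.694 of the counts in 15-KETE libraries and 5.05% ± 2.17 in controls (SD, n = 3 each, exact permutation test, p = 0.6). Control replicate 2 had the highest share, 7.41% (Wilson 95% interval 7.4 to 7.42), and the other 5 libraries lay between 3.14% (3.13 to 3.14) and 4.61% (4.6 to 4.62). Without it the difference of -1.11 points became 0.0695. Mitochondrial transcripts took 4.99% ± 0.522 and 4.75% ± 0.933 (exact p = 0.8, n = 3 each). The 10 most abundant genes took 5.64% ± 0.216 and 5.67% ± 0.312 (exact p = 0.9, n = 3 each), and replication-dependent histones 0.00136% ± 0.000542 and 0.00163% ± 0.000972 (exact p = 0.7, n = 3 each). These 3 differences also changed sign without control replicate 2, from 0.245 to -0.205, from -0.0365 to 0.0269 and from -0.000276 to 0.000285 points. None of these differences exceeded the spread between replicates, in a design whose smallest possible p is 0.1.

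The comparison of 15-KETE with control asked which transcripts of airway epithelial cells the metabolite alters. No single gene passed the test, and 5 genes chosen after their values were seen lay at overlapping levels in both groups. HMOX1, which degrades haem, had 7.9 ± 1.29 CPM in 15-KETE and 9.85 ± 3.78 in control libraries (SD, n = 3 each here and below). NQO1, a quinone reductase, had 147 ± 47.4 and 193 ± 112 CPM, and the inducible chaperone HSPA1A had 90.9 ± 60.3 and 143 ± 135. PTGR1, a reductase of keto-eicosanoids, had 178 ± 43.5 and 238 ± 129 CPM, and the cytokine IL6 36.7 ± 24.7 and 38.6 ± 22.8. In HMOX1, NQO1, HSPA1A and PTGR1 the highest value was that of control replicate 2. The fixed list of NRF2 targets, the genes that electrophiles raise through that factor, had a median log2 fold change of -0.14 (camera adjusted p = 0.05, not past the threshold) and passed as lower with the replicate number as a block (-0.13, camera adjusted p = 0.0338, and adjusted p = 0.831 with an estimated correlation), a call that ended with the length and GC correction (-0.08, camera adjusted p = 0.188).

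**Figure D2:**
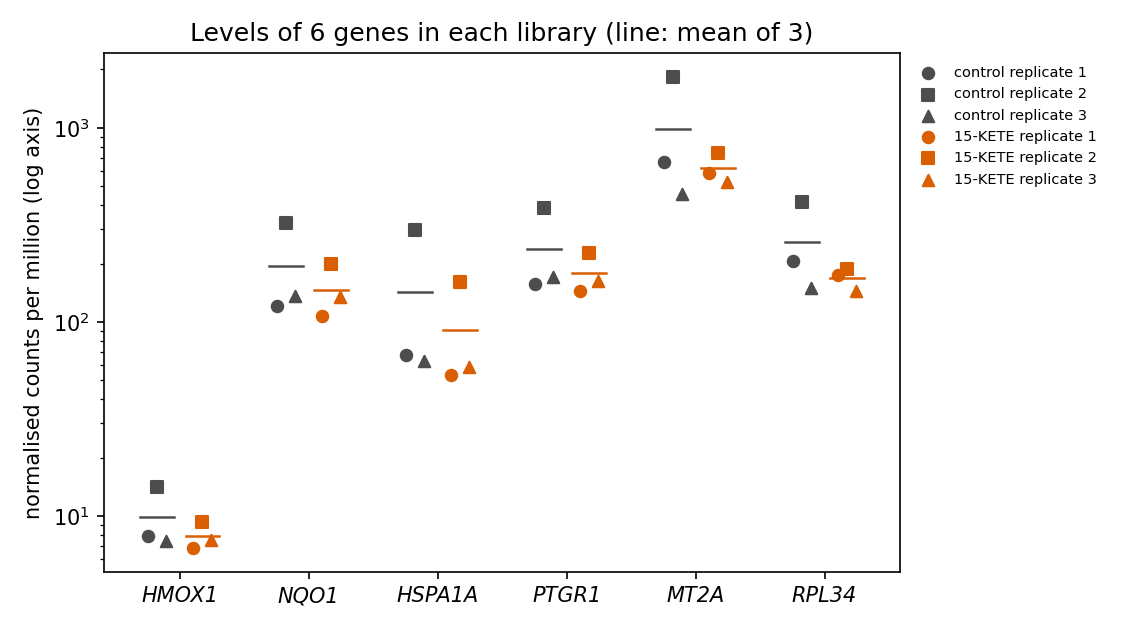
Normalised levels (CPM) of 6 genes in each library, on a log axis, with controls in grey, 15-KETE in orange, a marker shape per replicate number and a line at the mean of 3. Control replicate 2 is the highest library for each gene shown, as for NQO1 and RPL34, and the groups overlap.

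Of the 15451 genes tested with edgeR's quasi-likelihood test, 0 had an adjusted p below 0.05, and the smallest adjusted p was 0.9996. Unadjusted p was below 0.05 for 25 genes, where chance gives about 773 if the libraries share no structure by replicate number. DESeq2, limma-voom and limma-trend on FPKM also called 0 genes, with 68, 32 and 50 at an unadjusted p below 0.05. With the replicate number as a block, edgeR again called 0 genes (smallest adjusted p 0.695), with 727 genes at an unadjusted p below 0.05. The groups did not overlap for 355 genes (2.3%). With 3 against 3 libraries, chance gives a share of 0.1 if the libraries share no structure by replicate number. In the blocked fit the 95% interval of the fold change lay within 2-fold in either direction for 12153 genes (78.7%), and for 9547 of the 9813 genes above 10 CPM (97.3%). The fit without the block bounded fewer, 7829 genes (50.7%) and 6664 of the 9813 above 10 CPM (67.9%). In simulated counts, the fit without the block recovered 0 of 50 genes changed 1.5-fold, 2-fold, 3-fold or 4-fold, while the blocked fit recovered 9, 31, 41 and 44 of 50. The unblocked fit made 0 false calls and the blocked fit 10, and the 95% intervals held the true change for 100% of these genes without the block and for 92% to 98% with it. Without both replicate 3 libraries the blocked fit called 12 genes, all higher in 15-KETE, among them the atypical cadherin FAT1 (log2 fold change 1.23, edgeR adjusted p = 0.0373) and the NF-kB subunit REL (1.28, edgeR adjusted p = 0.0378), against adjusted p = 0.695 for both over all pairs. In the pair left out, the log2 differences of the 12 genes lay between -0.18 and 0.165, with FAT1 at -0.003 and REL at 0.012. Without both replicate 1 libraries the blocked fit called the splicing factor U2AF1 alone, whose reads can be shared with a near-identical copy (1.46, edgeR adjusted p = 0.0471, against 0.716 over all pairs). FAT1, REL and U2AF1 were chosen after their values were seen.

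The 20 genes of smallest p were of low abundance, with group means of 0.183 to 4.16 CPM, and each had an edgeR adjusted p of 0.9996. SSUH2 (ENSG00000125046, chromosome 3, 8619386 to 8745040) had 0.678 ± 0.123 CPM in 15-KETE and 0.183 ± 0.038 in control libraries, a log2 fold change of 1.85 ± 0.567 (SE). IGFBP5 (ENSG00000115461, chromosome 2, 216672105 to 216695549), which binds insulin-like growth factors, had 1.21 ± 0.387 and 0.438 ± 0.0143 CPM (1.46 ± 0.476, SE). The Wnt ligand WNT7B (ENSG00000188064, chromosome 22, 45920366 to 45977162) had 0.37 ± 0.0575 and 0.907 ± 0.196 CPM (-1.28 ± 0.487, SE). The others above 0 were LINC00654 (1.3), the ubiquitin ligase TRIM9 (1.22), CD109-AS1 (1.51), DCUN1D2-AS (1.65), ZNF488 (1.22), ZKSCAN7-AS1 (1.65), CHRDL2 (1.31), the unnamed ENSG00000258559 (1.29) and ENSG00000235036 (1.04), and another unnamed gene. Those below 0 were LINC01703 (-1.23), the pseudogenes SNRPFP1 (-1.57) and ANXA2P1 (-1.32), the gluconokinase IDNK (-1.2), CFAP300 (-0.89), the spectrin SPTBN4 (-0.89) and the unnamed ENSG00000273702 (-1.33), as log2 fold changes.

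Among the fixed lists, 4 of 29 were lower in 15-KETE than the other genes, and all 4 hold abundant genes of protein synthesis, respiration and protein quality control. Transcripts of the cytosolic ribosomal proteins had a median log2 fold change of -0.5 with 0 of 53 members above 0 (camera adjusted p = 9.97e-17). The nuclear-encoded subunits of oxidative phosphorylation had a median of -0.5 with 1 of 42 above 0 (camera adjusted p = 1.78e-13). Proteasome and autophagy genes had -0.23 with 3 of 28 above 0 (camera adjusted p = 0.000841), and heat shock genes -0.21 with 1 of 24 above 0 (camera adjusted p = 0.00941). With an estimated correlation between genes, adjusted p = 0.91 for each of these 4 lists. In simulated counts with 23 heat shock genes raised 1.5-fold, that list passed with the preset correlation (camera adjusted p = 4.41e-15, and 1.8e-21 with the block). It did not pass with an estimated one (camera adjusted p = 0.967, and 0.239 with the block), so the estimated correlation missed that change there. Beyond the effect of replicate number, those counts were drawn independently for each gene. They cannot tell which correlation suits the real lists, whose members can vary together. No member passed over all genes tested, and 0 members of any list passed when adjusted over the list alone, with or without the block. The members of smallest p were RPL34 (168 ± 21.8 CPM in 15-KETE and 257 ± 141 in control), the ATP synthase subunit ATP5F1D (23.6 ± 5.72 and 45.2 ± 37.6), the proteasome subunit PSMB6 (86.9 ± 23.1 and 139 ± 93.5) and the mitochondrial chaperonin HSPE1 (152 ± 23.2 and 236 ± 143).

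The 4 lower lists differed most in the replicate 2 pair, which holds the library with the largest share of ribosomal protein counts, control replicate 2. In that library genes of short exonic length had more of the counts. Across genes outside the lists its deviation from the mean of the 6 libraries correlated with length at a Spearman rho of -0.397 (-0.112 to 0.313 in the other libraries). The median exonic length per count there was 4777 bases, against 5529 to 6118. With the length and GC correction and no block, the 4 lists still passed by camera, with medians of -0.35 for ribosomal proteins, -0.28 for oxidative phosphorylation, -0.21 for proteasome and autophagy and -0.15 for heat shock genes. Within pairs, the ribosomal protein list had medians of -0.24, -0.97 and 0.03 for replicates 1, 2 and 3, and oxidative phosphorylation -0.21, -0.95 and 0.01. The medians of proteasome and autophagy genes were -0.12, -0.55 and 0.00, and those of heat shock genes -0.14, -0.37 and -0.04. Without control replicate 2 the medians were 0.05 for ribosomal proteins, 0.05 for oxidative phosphorylation, 0.04 for proteasome and autophagy and 0.09 for heat shock genes, and none of the 4 passed. Replication-dependent histones (0.31, over 7 tested members with few counts) and PPAR targets (0.14) did pass, both higher in 15-KETE. Heat shock genes also did not pass without 15-KETE replicate 1 or 15-KETE replicate 3, nor proteasome and autophagy genes without 15-KETE replicate 3. Without both replicate 2 libraries, all 4 passed as lower in the blocked fit at smaller sizes, with medians of -0.11 for ribosomal proteins, -0.12 for oxidative phosphorylation, -0.06 for proteasome and autophagy and -0.09 for heat shock genes. The number of lists past the threshold was 8, 2 and 9 without control replicates 1, 2 and 3, and 4, 10 and 3 without 15-KETE replicates 1, 2 and 3.

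**Figure D3:**
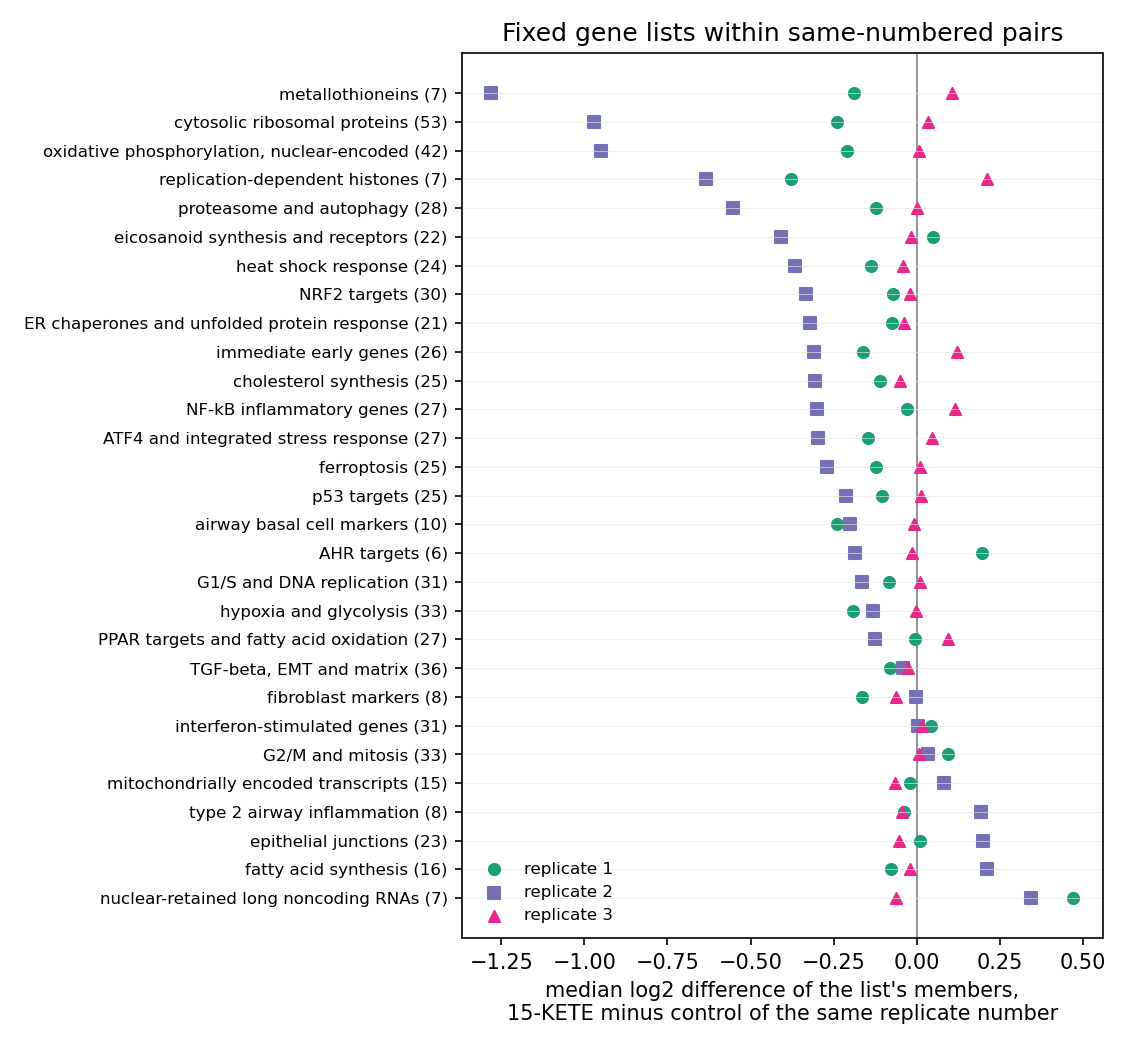
Median log2 difference between 15-KETE and control of the same replicate number, for the 29 tested lists with the number of tested members in brackets and a marker per replicate number. The replicate 2 pair lies farthest below 0 for metallothioneins (-1.28) and ribosomal proteins (-0.97), while the replicate 3 pair lies near 0 for these lists (0.11 and 0.03).

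With the replicate number as a block, 9 lists passed, including the same 4. NRF2 targets (median -0.13), cholesterol synthesis (-0.15), metallothioneins (-0.42) and hypoxia and glycolysis genes (-0.12) were lower, each with a camera adjusted p of 0.0338, where the settings fixed in advance ranged from 0.00292 to 0.946. Nuclear-retained long noncoding RNAs, such as TUG1, were higher (median 0.34, camera adjusted p = 0.00936, range 0.00292 to 0.946). With an estimated correlation, 0 lists passed with the block (smallest adjusted p = 0.831), and 0 had an unadjusted p below 0.05. Without the block the adjusted p was 0.05, just not past the threshold, for NRF2 targets (median -0.14, 9 of 30 above 0) and metallothioneins (-0.67, 1 of 7 above 0). It was 0.0952 for cholesterol synthesis (-0.15), hypoxia and glycolysis (-0.11) and the noncoding RNAs (0.26), all by camera. Without the block, each of these 5 lists passed when some single libraries were left out, such as NRF2 targets without control replicate 1 (-0.22) or 15-KETE replicate 2 (-0.23), cholesterol synthesis without the same libraries (-0.33 and -0.23) and metallothioneins without control replicate 1 (-0.77) or 3 (-0.93). Hypoxia and glycolysis genes and the noncoding RNAs passed without control replicate 3 (-0.23 and 0.75) or 15-KETE replicate 2 (-0.2 and 0.41). Without control replicate 2, none of the 5 passed and their medians lay on the other side of 0, at 0.05 for NRF2 targets, 0.11 for cholesterol synthesis, 0.06 for metallothioneins, 0.01 for hypoxia and glycolysis and -0.04 for the noncoding RNAs. With the length and GC correction added to the block, 3 of the 5 did not pass: NRF2 targets (median -0.08, camera adjusted p = 0.188), metallothioneins (-0.18, 0.265) and the noncoding RNAs (0.12, 0.505). The members of smallest p were the aldo-keto reductase AKR1C3 (log2 fold change -0.68 ± 0.38, SE), EBP (-0.7 ± 0.448), MT1X (-0.67 ± 0.37), BNIP3 (-0.35 ± 0.25) and TUG1 (0.36 ± 0.458).

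No list of inflammatory or lipid-mediator genes passed the test. NF-kB inflammatory genes had a median log2 fold change of -0.09 (11 of 27 above 0, camera adjusted p = 0.783), and NFKBIA, the inhibitor of NF-kB, had -0.33 ± 0.334 (SE). Interferon-stimulated genes had a median of 0.01 and a mean of -0.01 (camera adjusted p = 0.783), and ISG15 had -0.85 ± 0.444. Type 2 airway inflammation genes had -0.07 over the 8 tested of 31 (camera adjusted p = 0.914), with CISH at -0.31 ± 0.413. Genes of eicosanoid synthesis and receptors had -0.13 (10 of 22 above 0, camera adjusted p = 0.783). HPGD had 27 counts, ALOX15 7 counts and the oxo-eicosanoid receptor OXER1 6 counts over all 6 libraries together, which was too few to test. PPAR targets had 0.08 (camera adjusted p = 0.605), with the thioesterase ACOT1, whose reads can be shared with ACOT2, at -0.88 ± 0.384. The PPAR list passed without control replicate 2 (median 0.14). Fatty acid synthesis had 0.06 (camera adjusted p = 0.657, ACACA 0.38 ± 0.306), and ferroptosis genes -0.14 (camera adjusted p = 0.348, GPX4 -0.62 ± 0.479).

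Other stress and growth lists did not pass either. ATF4 targets had a median of -0.17 (camera adjusted p = 0.402, CEBPB -0.51 ± 0.435, SE) and passed without control replicate 1 (0.43, higher), control replicate 3 (-0.4, lower) or 15-KETE replicate 1 (-0.51, lower). ER chaperones had -0.14 (camera adjusted p = 0.184, SDF2L1 -0.86 ± 0.562) and p53 targets -0.13 (0.348, GADD45A -0.47 ± 0.309). AHR targets had a median of 0.01 but a mean of -0.23 (camera adjusted p = 0.605, ALDH3A1 -1.29 ± 0.67). G1/S genes had -0.08 (camera adjusted p = 0.348, PCNA -0.51 ± 0.4), G2/M genes -0.00 (0.783, UBE2C -0.37 ± 0.277) and immediate early genes -0.12 (0.57, NR4A2 0.46 ± 0.388). G1/S genes passed without control replicate 3 (-0.22) or 15-KETE replicate 2 (-0.27), and G2/M genes without 15-KETE replicate 3 (-0.22), all lower. Mitochondrially encoded transcripts had a median of 0.03, a mean of -0.03 and a test direction below 0 (camera adjusted p = 0.783, MT-ND3 -0.35 ± 0.266). Replication-dependent histones had -0.38 over 7 tested members (camera adjusted p = 0.425, H1-4 -0.99 ± 0.667), and passed without control replicate 2 (0.31, higher) or 15-KETE replicate 2 (-0.78, lower). Histone transcripts took only 0.00136% of the counts in 15-KETE and 0.00163% in control libraries. Each of the list members named here and above had an edgeR adjusted p of 0.9996.

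No list of epithelial state or of other cell types passed the test. TGF-beta, EMT and matrix genes had a median of -0.00 and a test direction above 0 (camera adjusted p = 0.914, MMP9 -0.97 ± 0.706, SE), and epithelial junction genes 0.09 (0.605, EPCAM -0.69 ± 0.553). Airway basal cell markers had -0.15 (camera adjusted p = 0.348, S100A2 -0.87 ± 0.507) and fibroblast markers -0.06 (0.57, S100A4 -0.92 ± 0.455). Secretory, ciliated and leukocyte markers had 3, 4 and 4 tested members and were not tested as sets. Their members of smallest p were the protease inhibitor SLPI (43.3 ± 28 CPM in 15-KETE and 83 ± 89.7 in control), the dynein DNAH5 (0.877 ± 0.556 and 0.635 ± 0.119) and CORO1A (7.87 ± 1.8 and 9.95 ± 1.92). The mucin MUC5B had 10 counts, the ciliogenesis factor FOXJ1 2 counts and the leukocyte antigen PTPRC 18 counts over all 6 libraries together.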

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

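The length and GC correction and the fits without a same-numbered pair were chosen after seeing the data. The count of 0 changed genes held in every other fit run, with 9 to 893 genes at an unadjusted p below 0.05 (8 in the test against 1.5-fold) and smallest adjusted p from 0.181 to 1. It moved only in blocked edgeR fits without a pair, to 1 gene without pair 1 and 12 genes without pair 3, all higher and all at least 2-fold, and the cause was not tested. Of 765 values of the named genes under the settings fixed in advance, 0 passed and 11 turned direction. The count of 4 lists became 9 with the replicate block, 0 with an estimated correlation, 0 with fry (also 0 unadjusted), 2 to 10 without 1 library, 7 with the length and GC correction and replicate block, and 9 without pair 2 with the replicate block. The 7 lists included mitochondrially encoded transcripts, higher at a median of 0.29. They left out 3 of the 9: metallothioneins (blocked median -0.42, quartiles -0.54 to -0.04, and -0.18, -0.31 to 0.12, after the correction), NRF2 targets (-0.13, -0.31 to 0.03, and -0.08, -0.17 to 0.07) and nuclear noncoding RNAs (0.34, 0.16 to 0.47, and 0.12, -0.00 to 0.2). These 3 kept 35.7% to 60.3% of their blocked median and the 6 that still passed 64.6% to 90%, and the cause was not tested. The block changed no other call. The differences in the 4 shares of counts moved by less than the SD of the control libraries, control replicate 2 included, with another denominator and without any 1 library. Without control replicate 2, those of ribosomal proteins (from -1.11 to 0.0695 points) and histones (from -0.000276 to 0.000285) moved by more than the 15-KETE SD (0.694 and 0.000542). All 4 changed sign without control replicate 2, that of mitochondrial transcripts also without 15-KETE replicate 3 (-0.0471 points) and that of the top 10 genes without control replicate 3 (0.0778) or 15-KETE replicate 1 (0.073). Library size alone as the scaling shifted the median of all genes by 0.0737 on the log2 scale. Pseudocounts and filters on FPKM alone were not run, because counts were used, and no comparison by the authors was used here.

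Without control replicate 2, 16 lists turned direction by the list test. The lists that turned without some library had these ranges of the median log2 fold change over the 6 fits without 1 library: metallothioneins -0.931 to 0.0631, ribosomal proteins -0.776 to 0.0459, oxidative phosphorylation -0.747 to 0.0458, histones -0.791 to 0.312, proteasome and autophagy -0.344 to 0.0402, heat shock -0.427 to 0.0873, ATF4 targets -0.513 to 0.431, cholesterol synthesis -0.333 to 0.105, ferroptosis -0.236 to 0.0204, NRF2 targets -0.23 to 0.048, eicosanoid genes -0.253 to 0.0801, immediate early genes -0.228 to 0.137, NF-kB genes -0.118 to 0.0831, G1/S -0.268 to 0.0897, type 2 inflammation -0.0957 to 0.243, fibroblast markers -0.261 to 0.0342, G2/M -0.218 to 0.19, TGF-beta -0.052 to 0.103, interferon genes -0.0456 to 0.237, mitochondrial transcripts -0.0794 to 0.138, fatty acid synthesis -0.0597 to 0.103, PPAR targets 0.0057 to 0.141, junctions -0.0901 to 0.152 and nuclear noncoding RNAs -0.0427 to 0.746. The named genes that turned were SLPI with -1.62 to 0.469, S100A2 -1.17 to 0.0457, SDF2L1 -1.2 to 0.226, EBP -0.965 to 0.0546, EPCAM -1.01 to 0.0724, PSMB6 -0.959 to 0.0287, GPX4 -0.954 to 0.0896, PCNA -0.769 to 0.0315, CEBPB -0.804 to 0.143, NFKBIA -0.485 to 0.105 and DNAH5 -0.186 to 0.718. AHR targets turned with a filter of 1 CPM in 3 samples (median 0.0313), and G2/M (0.00609) and TGF-beta (-0.0286) with the replicate block. The cause of these turns was not tested.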

Other observations

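The comparisons of replicate numbers, the length and GC correction, the fits without a pair, and the tests on the pairs, on control replicate 2, on ER chaperones, on corrected mitotic genes and on splits of the gene test were chosen after seeing the data. Replicate number, over both groups, went with far larger differences than 15-KETE did. In the blocked edgeR fit, 5163 of 15451 genes differed between replicate numbers at an adjusted p below 0.05. Both replicate 1 libraries had high transcripts of ATF4 targets, the genes of the amino acid and integrated stress response. In replicate 1, 19 of the 27 members were higher than the mean of replicates 2 and 3 and 1 was lower (DDIT4, -1.08 on the log2 scale, edgeR adjusted p = 0.0188), with a median log2 difference of 0.92 (camera adjusted p = 2.96e-40, and adjusted p = 0.605 with an estimated correlation). The same list was lower in replicate 3 than the mean of replicates 1 and 2, with 19 of 27 members lower and 0 higher. Its median there was -0.79 (camera adjusted p = 5.39e-12, and adjusted p = 0.579 with an estimated correlation). Each replicate number was set against the mean of the other 2, so these comparisons are not independent. High values in replicate 1 alone lower the replicate 3 difference. ATF4 itself had 622, 503 and 246 CPM in control replicates 1, 2 and 3, and 558, 316 and 257 in 15-KETE. ASNS, which makes asparagine, had 21.8 CPM in control and 28.4 in 15-KETE replicate 1, against 2.26 to 3.96 in the other libraries (edgeR adjusted p = 3.06e-05). CHAC1, which degrades glutathione, had 13.9 and 12.5 CPM against 1.25 to 2.05 (edgeR adjusted p = 6.86e-05), and DDIT3, the stress factor CHOP, 60.5 and 60.6 against 12.9 to 30.5 (edgeR adjusted p = 0.00112). KLF2, GPNMB and CREBRF were also higher, by 3.31, 2.26 and 2.4 on the log2 scale. The inflammatory genes IL6 (12.7 and 12.4 CPM against 36 to 61.7) and CXCL1 (39 and 30.5 against 128 to 238) were lower, each at an edgeR adjusted p of 0.000804. Of the 27 tested NF-kB inflammatory genes, 8 were lower and 1 was higher in replicate 1, and the others did not pass. The median of that list was -0.31 (quartiles -1.21 to 0.4, camera adjusted p = 0.000116, and adjusted p = 0.828 with an estimated correlation).

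Both replicate 2 libraries had high HSPA1A (299 and 160.5 CPM against 53.4 to 67.9), the hair keratin KRT81 (260 and 158 against 51.4 to 68.5) and the secreted protease inhibitors SLPI (186 and 75.5 against 24.8 to 37.2) and PI3 (73.6 and 40.1 against 7.32 to 23), each at an edgeR adjusted p of 0.000943. PI3 and SLPI have short exonic lengths of 551 and 596 bases. Genes with long exonic lengths, such as KIAA1109 (45272 bases, -2.13 on the log2 scale) and GOLGA4 (10837 bases, -1.73), were lower in replicate 2. There, 51 of 53 ribosomal protein genes and 37 of 42 oxidative phosphorylation genes were higher than the mean of replicates 1 and 3. The medians of these lists were 0.89 and 0.84 (camera adjusted p = 0.585 for both with an estimated correlation). Across genes outside the lists, the replicate 2 difference correlated with length at a Spearman rho of -0.352 and with GC content at 0.439, and 5 of 7 nuclear-retained noncoding RNAs were lower (median -0.81). After the length and GC correction the medians were 0.56 for ribosomal proteins, 0.53 for oxidative phosphorylation and -0.11 for the noncoding RNAs. Both replicate 3 libraries had high transcripts of part of the G2/M list. The kinetochore motor CENPE had 257 and 235 CPM against 21.1 to 42.2 (edgeR adjusted p = 6.81e-05). The spindle protein ASPM, which is not in that list, had 370 and 359 against 39 to 101 (edgeR adjusted p = 9.61e-05). Other genes of long exonic length outside the list were also higher, such as CEP290 (2.3 on the log2 scale, exonic length 25131 bases) and CCDC88A (2.17, 33942 bases). Of the 33 tested G2/M genes, 14 were higher there and 0 were lower (camera adjusted p = 2.43e-07, and adjusted p = 0.579 with an estimated correlation), while others did not pass, such as PLK1 (log2 difference 0.29), TPX2 (0.13) and KIF2C (-0.16). In replicate 3, 4 of 7 nuclear-retained noncoding RNAs were higher (median 1.03, camera adjusted p = 0.000336), and 39 of 53 ribosomal protein genes and 18 of 42 oxidative phosphorylation genes were lower (medians of -0.8 and -0.61), each list at adjusted p = 0.579 with an estimated correlation. After the length and GC correction these medians were 0.12, at a camera adjusted p of 0.39, -0.48 and -0.34.

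The first pattern weighed was the lower median of the 95 ribosomal protein and oxidative phosphorylation genes in 15-KETE. A fall shared by all pairs is argued against, because 34 of the 95 members were lower in pair 3, while 92 were lower in pair 1 and 94 in pair 2. The 92 of 95 members lower in pair 1 show that lower values were not confined to the pair of control replicate 2. Members of these lists move together, so each pair gives a single difference between libraries and not 95 replicates. The length trend also differed within pair 1, at a Spearman rho of -0.01 in the control and 0.189 in the 15-KETE library. Pair 1, a single difference, therefore cannot decide whether control replicate 2 alone is the source of the lower median. The blocked median without both replicate 2 libraries, -0.114 (quartiles -0.14 to -0.07) from -0.38, only restates the medians of pairs 1 and 3 (-0.24 and 0.03, against -0.96 in pair 2) and decides nothing. Whether control replicate 2 or its partner makes the pair differ cannot be told apart: both lie above the other libraries of their group in these genes, by 1.28 (quartiles 1.12 to 1.47) in control and 0.44 (0.34 to 0.53) in 15-KETE replicate 2, and the unblocked median without control replicate 2, 0.0459 (quartiles 0.00 to 0.08), leaves that partner unpaired. Taking out the length and GC trend moved the blocked median from -0.38 to -0.26 (quartiles -0.37 to -0.18), a smaller loss than the bound set in advance, but the members' quartiles, a reading added after the value was seen, lie on both sides of that bound, so part of the difference and such a trend cannot be told apart, and an effect of 15-KETE in some replicates stays open, untested.

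The second pattern was the ATF4 list in replicate 1. This list was also lower in replicate 3 (median -0.79), but the mean it was set against there holds replicate 1. That comparison therefore cannot tell whether replicate 3 departs by itself. Taking out the length and GC trend left the list's median log2 difference in replicate 1 at 0.97 (quartiles 0.67 to 1.51), against 0.92 before, which argues against that trend. The list of ER chaperones and unfolded protein response genes had a median of -0.0025 (quartiles -0.25 to 0.35), but 3 of its 21 members were higher and 0 lower in replicate 1: DNAJB9 (47.7 and 45.3 CPM against 15.6 to 28.5, edgeR adjusted p = 0.00548), HERPUD1 (154.5 and 154 against 48.2 to 128, 0.00788) and XBP1 (253 and 242 against 83.9 to 231, 0.0169). These 3 genes also had their lowest values in the replicate 3 libraries. The chaperone HSPA5 was not higher in replicate 1 (log2 difference -0.00, edgeR adjusted p = 0.998). An unfolded protein response in part of its targets therefore stays open, and no other biological explanation was tested.

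The third pattern was the mitotic genes in replicate 3. The 9 G2/M members with under 3 kb of exonic length had a median log2 difference of -0.00514 (quartiles -0.08 to 0.03), against 0.71 for the 24 longer ones, which goes with a length trend, and across genes outside the lists length correlated with this difference at a Spearman rho of 0.317. Both values met the rule set in advance for a length trend as the cause. Taking out the length and GC trend of genes outside the lists brought the short members to 0.37 (quartiles 0.25 to 0.43) and left the longer ones at 0.585 (quartiles 0.37 to 0.76). This reading, added after the data were seen, argues against the trend of other genes as the whole cause and leaves a part through length open. No biological explanation was tested, since the design names none for replicate 3.

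Splits of the 6 libraries into 3 and 3 number 10, too few for a share under 0.05. For genes the count of splits says nothing, because the real count was 0 and 10 of the 10 splits give as many by construction (highest other 0). For lists, 9 of the 10 gave as many, with 4 for the real split and 13 as the highest other. The 6 splits that keep 2 same-numbered pairs together gave 13, 13, 13, 9, 8 and 4 lists, the last no more than the real one, and 684 to 4445 genes at an unadjusted p below 0.05 against 25, which points to the structure of the samples by replicate number. Among the 4 splits that part all 3 pairs, lists numbered 4 for the real one and 6, 4 and 3 for the others, and blocked fits gave 9 lists and 727 genes at an unadjusted p below 0.05 for the real one against at most 7 lists and 676 genes.

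U2AF1, the gene called without pair 1, had log2 differences of -1.45, 1.44 and 1.44 in pairs 1, 2 and 3, and its counts are uncertain because the genome holds a near-identical copy. ACOT1, AKR1C3 and S100A4, each the member of smallest p of its list, which favours one sign in all pairs, had log2 differences of -0.91, -1.04 and -0.47, of -0.39, -0.68 and -0.8, and of -0.44, -1.03 and -0.96 in pairs 1, 2 and 3, each at an edgeR adjusted p of 0.695 with the block, so none passed.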
